A study of Homo sapiens with 6 samples.

How the data were processed

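Total RNA was isolated from Huh7 cells grown in DMEM and made into cDNA libraries, per the labels' protocols. The 6 libraries fall into 2 groups by their titles, 3 with a scrambled control hairpin and 3 with an EPHA2 hairpin, all 2 weeks after puromycin selection. How many hairpin sequences were used, and whether the libraries of a group came from separate cultures, is not stated in the labels. The submitters' processing notes list HISAT2 2.0.4 for alignment, HTSeq 0.6.1 for counting and genome build hg38. The annotation, the strand setting, the counting attribute and the normalisation tool are not given in the sources used here. Reads of a gene and of a gene overlapping it, or lying antisense to it, can therefore not be told apart, and reads of close paralogs are uncertain.

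The authors deposited 1 table of 16819 gene symbols by 6 libraries with normalised signal values to 4 decimals, 1 value per gene and library. In each library 100% of the values were whole multiples of a single step within a tolerance of 0.0001, which makes the deposited signal a gene read count divided by 1 size factor per library, uncorrected for gene length. The reads recovered in this way summed to between 6937938 and 11052320 per library. A count of 3 reads, the limit that a count of 0 allows, corresponded to 2.56 to 3.99 normalised read counts, and such limits cover counting error only. No row was 0 in all libraries, and 0 columns were left unused. Replicates were compared by a chi-square statistic of their reads per gene, which lay between 5.53 and 17.96, far above sampling noise, so that all 6 libraries counted separately.

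Gene positions came from GENCODE 29 on GRCh38, which placed 15967 of the symbols. RefSeq transcript numbers from the same release were known for 15463 symbols, or 91.9%, of which 9001 had 1 transcript and 6462 at least 2. Older symbols were matched through RefSeq synonyms where these were unique. Genes whose rows are missing from the table are not analysed here.

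The test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with lmFit and eBayes with an intensity trend, over all 6 libraries with the group as the only term. Genes entered with a mean of at least 1 over the 6 libraries, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p under 0.05. A fold change on this scale understates the change of genes with low values. SE is the moderated standard error of limma, and SD the spread of the deposited values. For EPHA2 an exact two-sided permutation test over all 20 assignments was added.

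Before the data were examined, 40 gene lists were fixed: signalling through the receptor and its known pathways, cell cycle and cell death, hepatocyte functions, stress responses, epithelial and adhesion genes, and markers of other cell types. The lists held 733 distinct genes, of which 572 were in the table. Lists with at least 5 tested members, 38 in all, were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry. The text names genes by a rule fixed at the same time. It takes EPHA2 in every library; the 10 largest rises and 10 largest falls among called genes of at least 2-fold change, mean above the median, groups that do not overlap and symbols that are no clone names or pseudogenes; up to 4 called members of a list that passed camera and up to 2 of any other list; and JAK1, STAT3, AKT1, AKT2, CCND1, MYC, BCL2L1, MCL1, SOCS3, CDKN1A, CDKN1B, AFP and ALB. Of the 10 falls 8 are named, and the others are not reported here. Genes named outside the rule are said to be so where they appear, or serve to describe the table, as GAPDH does.

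The alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 10, rescaling by median-ratio or TMM factors, quantile normalization, eBayes without the trend or with robust variance, the replicate number as a block, and leaving out each library in turn. Because whole reads were recovered, the edgeR 4.0.16 quasi-likelihood test and the DESeq2 1.42.0 Wald test were run on them as further alternatives. The edgeR test called 787 genes higher and 1211 lower of 8294 tested, and DESeq2 847 and 1132. Whether replicate numbers pair the samples was checked by correlating deviations from the group means. A fit to genes with 1 RefSeq transcript only was added after seeing the data.

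The limma test was tested on simulated reads drawn from the real means and library sizes, with 12660 genes in the step. Of genes changed 1.5-fold, 41.8% were recovered, of those changed 2-fold 77.6% and of those changed 4-fold 97.0%, and 11 of 166 calls were genes left unchanged. The changed genes were drawn only from those with a mean of at least 20, so recovery at lower values was not simulated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for recovery of the reads, tests of explanations and figures.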

Results

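RNA was sequenced from Huh7 cells, an established human liver cancer line, that carried either a short hairpin RNA (shRNA) against EPHA2 or a scrambled control hairpin. EPHA2 is a receptor tyrosine kinase of the Eph family that binds ephrins on neighbouring cells. Each of the 2 groups held 3 libraries, taken 2 weeks after puromycin selection of the transduced cells. The control libraries held 11052320, 9760177 and 10171389 reads assigned to genes, and the EPHA2 shRNA libraries 7609064, 8831643 and 6937938. Values are read counts per gene divided by 1 size factor per library, here called normalised read counts, and fold changes are on the log2 scale after adding 1. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The single comparison, EPHA2 shRNA against control shRNA, addresses which transcripts change when this receptor is depleted. Part of the interest is in the JAK1/STAT3 and AKT pathways, through which EPHA2 is reported to act in liver cancer cells.

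EPHA2 itself was lower in each of the 3 knockdown libraries than in any control library. Its normalised read count was 6627 ± 1386 (SD, n = 3) in control cells and 1237 ± 169.7 (SD, n = 3) after knockdown, so that 18.7% of the control level was left. Single libraries gave 5805, 8227 and 5849 in the controls and 1367, 1045 and 1299 in the knockdown. The log2 fold change was -2.41 (SE 0.13), with an adjusted p of 2.94e-08 in limma. An exact two-sided permutation test of the 6 log2 values gave p = 0.1, the smallest value that 3 against 3 samples allow. The gene lies on the minus strand of chromosome 1, from 16124337 to 16156087 in GRCh38 with GENCODE 29 gene bounds, and has 1 RefSeq transcript.

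Among 12877 genes tested, 621 were higher and 1296 lower after EPHA2 knockdown at an adjusted p under 0.05 in limma, together 14.9% of the genes. A change of at least 2-fold was reached by 130 of the higher and 491 of the lower genes, the former count being 85 without EPHA2 shRNA replicate 1 and 177 with quantile normalization. In 31.9% of the tested genes the values of both groups did not overlap, where chance gives 10%. The first principal component held 34.1% of the variance and separated the groups. Counts moved with the processing: quantile normalization gave 938 higher and 1043 lower genes, DESeq2 on the recovered reads 847 and 1132, and limma without an intensity trend 142 and 519. The share of called genes that were lower was 67.6%, against 52.7% with quantile normalization and 57.2% with DESeq2; 314 genes were higher without EPHA2 shRNA replicate 1 and 349 without EPHA2 shRNA replicate 2.

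**Figure D1:**
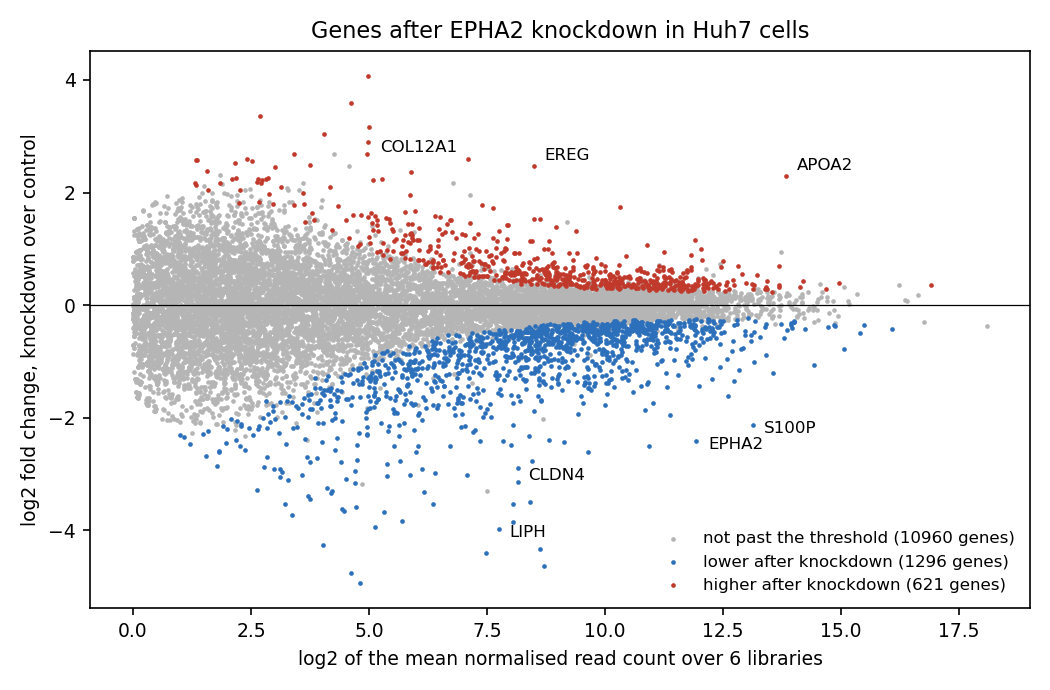
Log2 fold change of EPHA2 shRNA over control shRNA (vertical axis) against the log2 of the mean normalised read count over 6 libraries (horizontal axis), 1 point per gene for 12877 genes. The 621 genes higher after knockdown are red, the 1296 lower ones blue, and the lower genes reach larger changes, with LIPH at -3.98.

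The falls named here are of genes with different functions. Collectrin (CLTRN), a membrane protein that assists amino acid transport, fell from 630.7 ± 141 to 54.57 ± 7.929 normalised read counts (SD, n = 3 each). The membrane phospholipase LIPH had a log2 fold change of -3.98, the IGF-binding protein IGFBP5 of -3.85 and the carbonic anhydrase CA4 of -3.54. Those of the translation factor EEF1A2, of TMEM45B and of the cytidine deaminase CDA were -3.32, -3.14 and -3.02. FLOT1 met the naming rule with -3.53, but its control libraries stood at 451, 1043 and 29, and its call was lost without control shRNA replicate 1 (adjusted p = 0.0585), control shRNA replicate 2 (adjusted p = 0.0535) or EPHA2 shRNA replicate 2 (adjusted p = 0.0846), and with robust variance (adjusted p = 0.257). Its log2 fold change ran from -5.04 to -2.48 over the fits that left out 1 library.

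Among the rises was APOA2, an apolipoprotein of high-density lipoprotein, which went from 4962 ± 560 to 24460 ± 4030 normalised read counts (SD, n = 3 each). This was a 4.91-fold change with an adjusted p of 1.54e-08. Epiregulin (EREG), a ligand of the EGF receptor family, rose from 111.9 ± 19.85 to 616.2 ± 33.01, and fibroblast growth factor 2 (FGF2) from 91.15 ± 7.395 to 302.5 ± 12.43. The collagen gene COL12A1 rose by 2.60 on the log2 scale, the cation channel gene TRPC6 by 2.37, SUSD5 by 1.95 and the zinc finger homeobox gene ZFHX4 by 1.77. Neurotensin (NTS) went from 587.1 ± 63.67 to 1970 ± 239.1. RTL6 and MPPED1 rose by 1.68 and 1.65. For these 10 genes and for all falls named here but FLOT1, the call held in each of the 6 fits that left out 1 library.

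**Figure D2:**
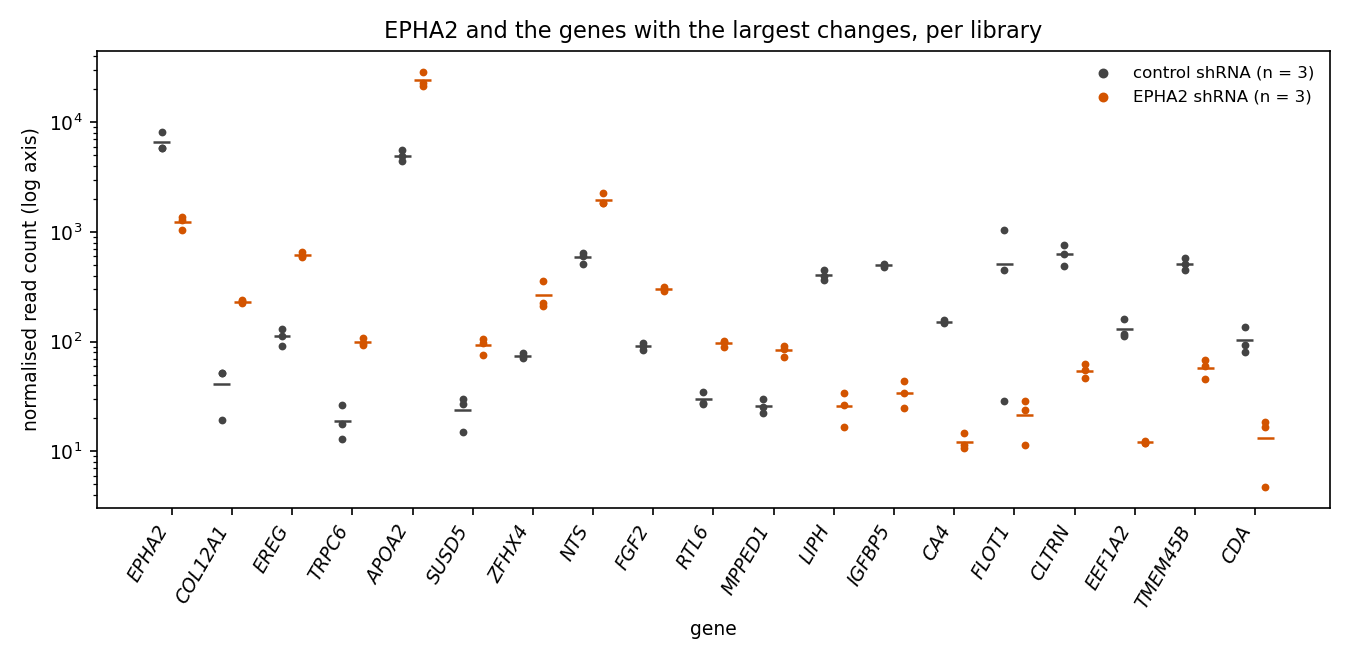
Normalised read counts (log axis) of EPHA2, the 10 largest rises that met the naming rule and the 8 falls named here, 1 point per library, with group means as bars for control shRNA (grey, n = 3) and EPHA2 shRNA (orange, n = 3). The 3 APOA2 points lie between 21632 and 29074 after knockdown and between 4437 and 5551 in control cells, while the FLOT1 control points spread from 29 to 1043.

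Of the 38 fixed gene lists with at least 5 tested members, 2 passed limma's camera test, which compares a list with all other genes. Among 17 tested G1/S cell cycle genes, 4 rose and 0 fell, and 6 rose when adjusted over the list alone, with a list median of 0.22 and an adjusted p of 0.01 (adjusted p = 0.552 with an estimated correlation). The risers were the DNA polymerase alpha subunit POLA1 (1.37-fold), the GINS subunit GINS1 (1.27-fold) and the replication licensing factors CDT1 (1.23-fold) and CDC6 (0.26 on the log2 scale). Among 15 tested epithelial junction and keratin genes, 0 rose and 6 fell, also 6 when adjusted over the list alone, with a median of -0.43 and an adjusted p of 0.0425 (adjusted p = 0.552 with an estimated correlation). Claudin-4 (CLDN4) fell from 500.6 ± 34.31 to 67.57 ± 14.49 normalised read counts (SD, n = 3 each), the adhesion molecule EPCAM by 0.68 on the log2 scale, keratin 19 (KRT19) by 0.57 and the splicing regulator ESRP2 by 0.52. KRT19 and ESRP2 were not called without an intensity trend (adjusted p = 0.111 and 0.0604). With a correlation estimated from the data, 0 of the 38 lists passed camera. Unadjusted camera p-values there were under 0.05 for 3 lists, the epithelial (0.031), ERK immediate-early and feedback (0.0438) and integrin and focal adhesion genes (0.0451). With the preset correlation these lists had unadjusted camera p-values of 0.00224, 0.00696 and 0.00751. Their estimated correlations were -0.032, 0 and 0, all under the preset 0.01, so correlated genes do not explain the higher values. The G1/S list had 0.0581 with an estimated correlation of 0.077. Of the 38 lists, 9 passed fry, which tests a list without comparing it with other genes. G1/S passed upward, and the epithelial, ERK, integrin, JAK and STAT, fatty acid oxidation, drug and bile acid metabolism, fetal liver and mesenchymal lists downward. The epithelial list also lost its call without control shRNA replicate 1 (adjusted p = 0.0976), and POLA1 (adjusted p up to 0.0595 over the fits that left out 1 library), GINS1 (0.108), CDT1 (0.123) and CDC6 (0.105) each lost theirs in at least 1 such fit, the largest values coming without EPHA2 shRNA replicate 2, EPHA2 shRNA replicate 1, control shRNA replicate 3 and control shRNA replicate 1.

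**Figure D3:**
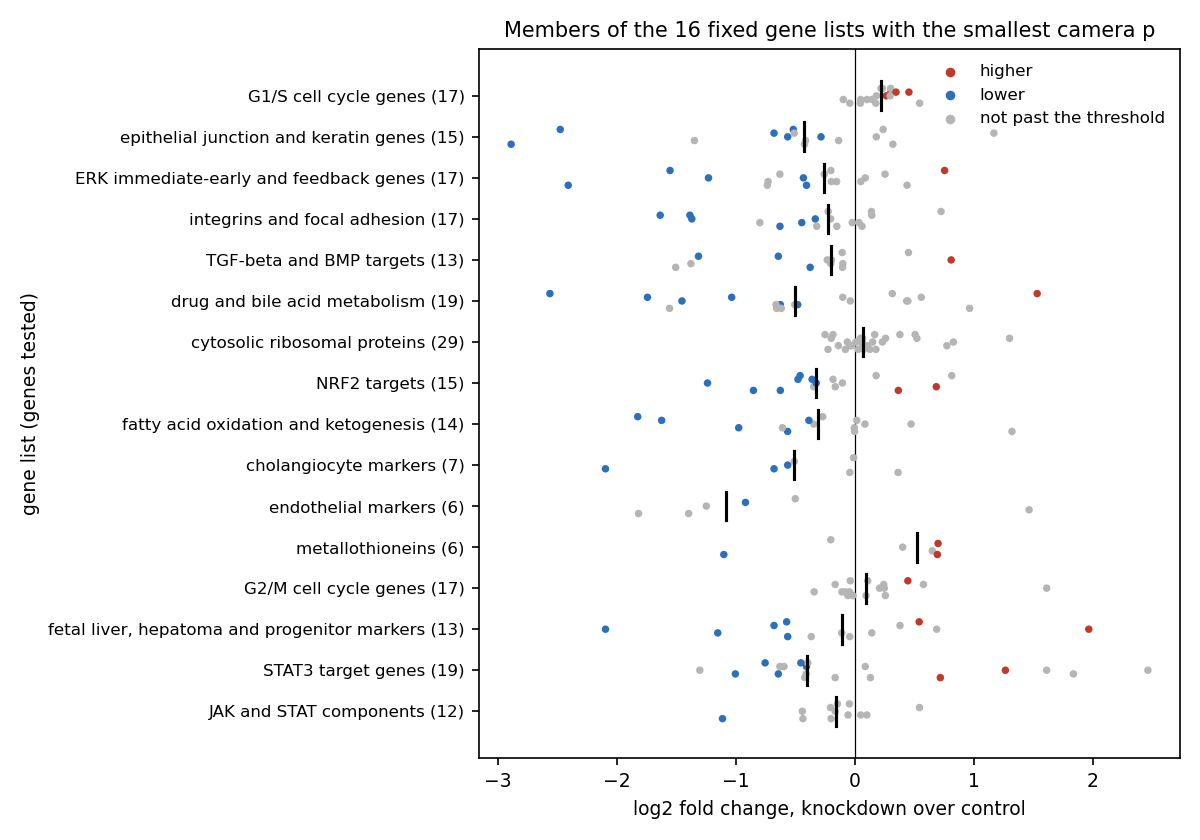
Log2 fold changes (EPHA2 shRNA over control shRNA) of the tested members of the 16 fixed lists with the smallest camera p, 1 point per gene, red or blue where the gene passed the threshold, with a black bar at the list median. The G1/S list has its median at 0.22 and the epithelial list at -0.43, and members of most other lists lie on both sides of 0.

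Members of the Eph family other than EPHA2 were called in both directions. Of 7 tested Eph receptors, EPHA2 included, 1 rose and 2 fell (3 and 2 adjusted over the list alone). Besides EPHA2 itself only EPHA1 fell, from 141.5 ± 14.06 to 52.8 ± 15.3 normalised read counts (SD, n = 3 each). The 1 receptor that rose was EPHB4, by 0.26 on the log2 scale, named here because it was the sole riser. Of 7 ephrins, the membrane-bound receptor ligands, 0 rose and 1 fell (0 and 1 adjusted over the list alone): EFNB3, by 1.64 on the log2 scale, with an adjusted p = 0.0695 without control shRNA replicate 1. Of 8 other receptor tyrosine kinases of hepatocytes and hepatoma, 1 rose and 1 fell (1 and 2 adjusted over the list alone). PDGFRA rose 2.20-fold and PDGFRB stood 1.44-fold lower. Over the fits that left out 1 library the adjusted p of PDGFRB reached 0.0769, without EPHA2 shRNA replicate 1. Its call was also lost with quantile normalization (adjusted p = 0.0691). Without an intensity trend neither gene was called (adjusted p = 0.0633 for PDGFRA and 0.132 for PDGFRB).

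Within the JAK1/STAT3 pathway, JAK1 was at 2506 ± 43 normalised read counts in control and 2407 ± 78.72 in knockdown cells (SD, n = 3 each), a log2 difference of -0.06 (SE 0.08) with an adjusted p of 0.697. Of 12 tested JAK and STAT components, 0 rose and 1 fell (0 and 1 adjusted over the list alone): OSMR, a receptor subunit for oncostatin M, from 778.3 ± 111.1 to 357.3 ± 28.22. The list did not pass camera (adjusted p = 0.528, and 0.887 with an estimated correlation) and passed fry downward (adjusted p = 0.00858). The fry pass was not particular to this list, as 9 lists passed. The integrin and fatty acid oxidation lists had the same fry adjusted p, and the ERK and epithelial lists 0.00539. Of 19 STAT3 target genes, 2 rose and 5 fell (3 and 8 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.528). TIMP1, an inhibitor of metalloproteinases, fell 2.01-fold, while the fibrinogen chain FGA rose 1.64-fold. Cyclin D1 (CCND1) fell from 18340 ± 2106 to 13810 ± 1373, with an adjusted p of 0.0117. Without an intensity trend CCND1 (adjusted p = 0.187), TIMP1 (0.0633) and FGA (0.103) were not called. MYC, at 1912 ± 134.2 and 2033 ± 202.3, differed by less than the test could call (adjusted p = 0.621). SOCS3, the feedback inhibitor of STAT3 signalling, had a log2 difference of 0.13 (SE 0.33), which was -0.32 without EPHA2 shRNA replicate 1. STAT3 and MCL1 were not analysed here.

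Of 9 tested AKT and PI3K components, 0 rose and 1 fell (1 and 1 adjusted over the list alone): RHEB, the GTPase that activates mTORC1, 1.28-fold. The RHEB call was lost without EPHA2 shRNA replicate 1 (adjusted p = 0.103), the highest value over the fits that left out 1 library. It was also lost without an intensity trend (adjusted p = 0.182). AKT1 was at 8.656 ± 2.611 and 4.5 ± 3.13 normalised read counts (SD, n = 3 each) and BCL2L1 at 6.8 ± 3.538 and 5.538 ± 0.9919. At such levels a difference between the groups was not detectable; the log2 difference of BCL2L1, -0.17, was 0.17 without control shRNA replicate 2. These genes have 3 and 8 RefSeq transcripts, a property that went with a lower median value in this table. AKT2 was not analysed here. The cell cycle inhibitor CDKN1B, at 2363 ± 7.415 and 2346 ± 157.5, had a log2 difference of -0.01 (SE 0.08) whose sign changed under several alternatives. CDKN1A had at most 0.971 normalised read counts in any library and was not tested. Of 19 FOXO target genes, which AKT holds down, 0 rose and 2 fell (1 and 4 adjusted over the list alone): CCNG2 fell 1.71-fold, and catalase (CAT) 1.35-fold, with an adjusted p = 0.0555 without control shRNA replicate 3.

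Of 17 tested ERK immediate-early and feedback genes, 1 rose and 5 fell (1 and 6 adjusted over the list alone), with a camera adjusted p of 0.0714. The list contains EPHA2. The ERK phosphatase gene DUSP5 fell from 4239 ± 126 to 1807 ± 136 normalised read counts (SD, n = 3 each). EGR1 (-1.56), ETV5 (-0.43) and CCND1 (-0.41) were the other fallers and SPRED1 (0.75) the riser. CCND1 belongs to the naming rule, while EGR1, ETV5 and SPRED1 were named after their values were seen. The list passed camera without EPHA2 shRNA replicate 3 (adjusted p = 0.0359), with no filter (0.037) and in edgeR on the recovered reads (0.033). It did not pass with an estimated correlation (adjusted p = 0.552), nor when members shared with other lists, EPHA2 among them, were dropped (0.287). It also failed camera with a mean of at least 10 (adjusted p = 0.183), median-ratio scaling (0.101), TMM scaling (0.0757) and among genes with 1 RefSeq transcript (0.139).

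In the integrin and mesenchymal lists all called genes fell, and in the YAP/TAZ, TGF-beta and WNT lists they went both ways. Of 17 integrins and focal adhesion genes, 0 rose and 6 fell (0 and 7 adjusted over the list alone), with a camera adjusted p of 0.0714 and 0.552 with an estimated correlation. This list passed camera in edgeR (adjusted p = 0.033), with no filter (0.0427) and among genes with 1 RefSeq transcript (0.0246). It also passed without control shRNA replicate 3 (0.039), EPHA2 shRNA replicate 1 (0.041) or EPHA2 shRNA replicate 2 (0.0456). It did not pass camera with a mean of at least 10 (adjusted p = 0.0829), median-ratio scaling (0.101), TMM scaling (0.0757) or members of 1 list only (0.0877). The fibronectin receptor subunit ITGA5 fell from 1512 ± 60.68 to 578.3 ± 45.4 normalised read counts (SD, n = 3 each), and ITGA3, a laminin receptor subunit, 2.59-fold. Of 17 mesenchymal transition genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone), among them the membrane metalloproteinase MMP14 (1.95-fold) and FSTL1 (1.64-fold). Of 15 YAP/TAZ targets, 3 rose and 3 fell (4 and 4 adjusted over the list alone): CTGF, a matrix protein also called CCN2, rose 1.75-fold, and DOCK5 fell 1.61-fold. Of 13 TGF-beta and BMP targets, 1 rose and 3 fell (1 and 5 adjusted over the list alone): CTGF rose, and hepcidin (HAMP), the liver hormone of iron balance, fell from 7083 ± 803.9 to 2858 ± 488.4. This list had a camera adjusted p of 0.141, 0.0359 without EPHA2 shRNA replicate 3, and 0.887 with an estimated correlation. Of 15 WNT/beta-catenin targets, 1 rose and 2 fell (1 and 2 adjusted over the list alone), with the WNT deacylase gene NOTUM 3.22-fold lower.

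Genes of hepatocyte function changed in both directions. Of 24 hepatocyte secreted proteins, 6 rose and 6 fell (8 and 9 adjusted over the list alone). APOA2 rose, and vitronectin (VTN) fell from 29690 ± 2296 to 14320 ± 2123 normalised read counts (SD, n = 3 each). Of 11 hepatocyte transcription factors, 2 rose and 1 fell (4 and 3 adjusted over the list alone): ONECUT1 rose 1.64-fold and NR0B2, the bile acid-induced repressor, fell 2.28-fold. Of 13 fetal liver, hepatoma and progenitor markers, 2 rose and 5 fell (2 and 6 adjusted over the list alone), with the trypsin inhibitor SPINK1 falling from 10140 ± 941.5 to 4593 ± 855.6 and EPCAM falling by 0.68 on the log2 scale. Alpha-fetoprotein (AFP) was at 315200 ± 19810 and 247900 ± 56640, with an adjusted p of 0.0875, and albumin (ALB) at 123400 ± 6659 and 101000 ± 9728, with an adjusted p of 0.0565. AFP took 2.43, 2.29 and 3.39% of the reads in the knockdown libraries and 3.12, 3.35 and 3.50% in the controls. Without EPHA2 shRNA replicate 3, whose share lies within the control range, the adjusted p was 0.000988 for AFP and 0.0111 for ALB. Other omissions raised it, to 0.299 for AFP without EPHA2 shRNA replicate 2 and to 0.23 for ALB without control shRNA replicate 3. In DESeq2 the adjusted p was 0.0625 for AFP and 0.0454 for ALB. The log2 fold change of AFP ran from -0.548 to -0.262 over the fits that left out 1 library. Its highest value over all 19 alternatives was 0. Quantile normalization gives 0 to any gene that ranks first in every library, whatever its change, so this end is not read as a lack of change.

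Of 19 drug and bile acid metabolism genes, 1 rose and 6 fell (1 and 7 adjusted over the list alone); the camera adjusted p was 0.141, 0.033 in edgeR, 0.434 among genes with 1 RefSeq transcript and 0.887 with an estimated correlation. The bile acid synthesis enzyme CYP27A1 fell from 1207 ± 14.64 to 587.9 ± 15.34 normalised read counts (SD, n = 3 each), and GSTA1, a glutathione transferase with near-identical paralogs whose reads are uncertain, 2.74-fold. Of 14 fatty acid oxidation and ketogenesis genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone): CPT1A, which controls fatty acid entry into mitochondria, fell from 116.1 ± 12.68 to 32 ± 3.523, and CPT2 1.48-fold. Of 11 fatty acid synthesis genes, 0 rose and 4 fell (1 and 4 adjusted over the list alone), including the lipid droplet lipase gene PNPLA3 (1.63-fold) and malic enzyme ME1 (1.38-fold). Of 19 cholesterol biosynthesis genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone): EBP fell 1.72-fold and MVD 1.44-fold. Of 15 glycolysis genes, 1 rose and 3 fell (2 and 4 adjusted over the list alone): the glucose transporter SLC2A3 fell from 241.5 ± 51.97 to 51.7 ± 20.37 and PGK1 1.44-fold. Of 12 hypoxia response genes, 0 rose and 2 fell (0 and 3 adjusted over the list alone): BHLHE40 fell 1.97-fold, and SLC2A1 1.28-fold. The SLC2A1 call was lost in edgeR (adjusted p = 0.0527), DESeq2 (0.0625), median-ratio scaling (0.0817) and quantile normalization (0.077), and without EPHA2 shRNA replicate 1 (0.175), control shRNA replicate 1 (0.0683) or control shRNA replicate 3 (0.134).

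The stress and innate response lists differed in how many members were called. Of 19 interferon-stimulated genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone). The ubiquitin-like modifier ISG15 fell from 407.4 ± 63.43 to 120.4 ± 8.825 normalised read counts (SD, n = 3 each). The RNA sensor gene IFIH1 went from 52.22 ± 8.911 to 23.03 ± 12.65 (adjusted p = 0.0279), a call lost in 6 alternatives, with an adjusted p of 0.119 without EPHA2 shRNA replicate 1. Of 15 NF-kB targets and cytokines, 1 rose and 3 fell (1 and 3 adjusted over the list alone); NFKBIA fell 1.58-fold, with an adjusted p = 0.062 without EPHA2 shRNA replicate 2, and CXCL8 1.85-fold, with an adjusted p = 0.0801 without that library. CXCL8 lost its call in DESeq2 (adjusted p = 0.0588) and with robust variance (0.24) too. Both genes also lost the call without EPHA2 shRNA replicate 1 (adjusted p = 0.0616 and 0.0682). Of 15 NRF2 targets, 2 rose and 7 fell (3 and 7 adjusted over the list alone): the aldo-keto reductase AKR1B10, which has close paralogs, fell 2.36-fold and OSGIN1 1.81-fold. Of 6 metallothioneins, metal-binding proteins of near-identical sequence whose reads are uncertain, 2 rose and 1 fell (3 and 1 adjusted over the list alone), with MT2A and MT1M both 1.62-fold higher. Of 15 unfolded protein response and ATF4 targets, 1 rose and 1 fell (1 and 1 adjusted over the list alone): the cystine transporter SLC7A11 rose 1.61-fold and DNAJB9 fell 1.43-fold. Of 14 p53 target genes, 1 rose and 2 fell (1 and 3 adjusted over the list alone): AEN rose 1.34-fold and TIGAR fell 1.34-fold. Over the fits that left out 1 library the adjusted p of TIGAR reached 0.0737, without control shRNA replicate 3. Its call was also lost with quantile normalization (adjusted p = 0.0588). Without an intensity trend neither gene was called (adjusted p = 0.105 for AEN and 0.134 for TIGAR). Of 14 apoptosis regulators, 0 rose and 1 fell (0 and 1 adjusted over the list alone): CFLAR, 1.55-fold, with an adjusted p = 0.0623 without control shRNA replicate 1.

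Of 17 G2/M cell cycle genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone): CENPF, a kinetochore protein, 1.36-fold, with an adjusted p = 0.0702 without EPHA2 shRNA replicate 2. Of 15 replication-dependent histone genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone): HIST2H2BE, 1.61-fold, with an adjusted p up to 0.0979 without control shRNA replicate 1. Of 8 genes of the RNA interference machinery, 0 rose and 1 fell (0 and 1 adjusted over the list alone): AGO4, 1.43-fold. Of 29 cytosolic ribosomal proteins, 0 rose and 0 fell in limma, also 0 when adjusted over the list alone; 7 had an unadjusted value under 0.05, edgeR called 0 and DESeq2 called 2. The ribosomal list had a camera adjusted p of 0.141, 0.0171, upward, without EPHA2 shRNA replicate 1, and 0.887 with an estimated correlation. The mitochondrially encoded genes were not analysed here. Median, mean and camera direction differed in sign for the ephrins, STAT3 targets, apoptosis regulators, cholesterol and fatty acid synthesis genes, histones, YAP/TAZ targets and fibroblast markers.

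Markers of other liver cell types were checked as well. Of 7 fibroblast and stellate cell markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone), namely PDGFRA and PDGFRB. Of 6 endothelial markers, 0 rose and 1 fell (0 and 2 adjusted over the list alone): PECAM1, from 324.9 ± 19.66 to 173.7 ± 39.18 normalised read counts (SD, n = 3 each). The endothelial list had a camera adjusted p of 0.225, 0.00938 over 5 members without EPHA2 shRNA replicate 3, and 0.887 with an estimated correlation. Of 7 cholangiocyte markers, 0 rose and 3 fell (0 and 3 adjusted over the list alone), with KRT19 and EPCAM shared with the epithelial list. Of 3 tested leukocyte markers, 0 rose and 0 fell in limma, 0 adjusted over the list alone, 0 at an unadjusted value under 0.05 and 0 in DESeq2. In edgeR, where 2 of the 3 were not tested, 0 were called, and the list was too short for camera.

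Genes with several RefSeq transcripts had lower median values than genes with 1. Among subunits of complexes that every cell uses, 173 genes with 1 RefSeq transcript had a median of 2058 normalised read counts and 171 genes with at least 2 a median of 8. The glycolytic enzyme GAPDH, abundant in most cells, was listed at 30.06 ± 1.924 in control cells (SD, n = 3). Of the tested genes, 7303 had 1 RefSeq transcript, and 20.2% of them were called; 4618 had at least 2, and 8.4% were called. In a fit restricted to the 7303 genes, an alternative added after seeing the data, 503 genes were higher and 1106 lower. Levels of different genes are therefore not compared here, and some genes with several transcripts that were not called, such as AKT1 and BCL2L1, were measured from few reads. Others were not, such as JAK1, which has 8. Called genes with several transcripts include COL12A1, FGF2 and CPT1A with 2, PDGFRA with 3, OSMR with 5 and CFLAR with 6. Which part of their reads was counted is not known, so their changes may not stand for the whole gene.

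**Figure D4:**
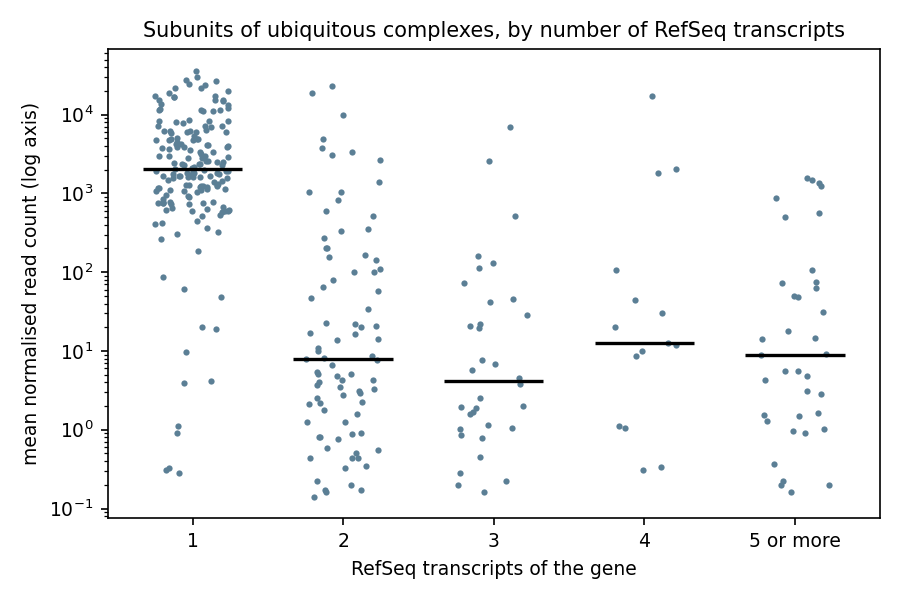
Mean normalised read count over 6 libraries (log axis) of subunits of ubiquitous complexes, by the number of RefSeq transcripts of the gene, 1 point per gene with a black bar at the median. Genes with 1 transcript have a median of 2058, and the bars of the classes with more transcripts lie lower.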

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

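The fit to genes with 1 RefSeq transcript was chosen only after the results were seen; all other alternatives were fixed before. EPHA2 kept its direction and call in all 19 alternatives, with log2 fold changes of -2.50 to -2.25. Of 1525 alternative values of the 81 other called genes picked by the naming rule, 1432 kept direction and call, 93 kept the direction and lost the call, and 0 reversed. Without an intensity trend 38 of the 81 genes lost their call, not all of them marked where they are named. Another 12 losses came without EPHA2 shRNA replicate 2. Among genes that were not called, CDKN1B changed sign to 0.035 with median-ratio scaling, 0.01 with quantile normalization, 0.023 in edgeR and 0.036 in DESeq2. In these settings the log2 fold changes of the tested genes moved upward by medians of 0.047, 0.07, 0.033 and 0.048. A shift of that size is enough to change the sign of CDKN1B, which stood at -0.012. No other cause was tested.

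Over the 6 fits that left out 1 library, CDKN1B ranged from -0.059 to 0.038, BCL2L1 from -0.476 to 0.174 and SOCS3 from -0.322 to 0.499. The number of genes higher ranged from 314 (without EPHA2 shRNA replicate 1; 349 without EPHA2 shRNA replicate 2) to 615, with fewer samples in each fit. The genes higher numbered 938 with quantile normalization. Without an intensity trend 142 genes were higher and 519 lower, and 581 of the 1917 calls were shared. The cause of these shifts was not tested.

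The 2 lists past camera became 1 with a pseudocount of 0.1, with a mean of at least 10, without an intensity trend and with members of 1 list only, 4 with no filter, 5 in edgeR and 0 with an estimated correlation. They ranged from 1 (without control shRNA replicate 1) to 5 (without EPHA2 shRNA replicate 3) over the fits that left out 1 library, with 4 without EPHA2 shRNA replicate 1. The G1/S list held its call in each of these except with an estimated correlation (adjusted p 0.00251 to 0.552 over its alternatives); the epithelial list lost it in 6 (0.00325 to 0.552). DESeq2 and robust variance gave no list value.

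With the replicate number as a block, 462 genes were higher and 1102 lower. Same-numbered libraries had correlations of deviations of 0.01, -0.17 and -0.11, so the numbers were not taken to pair the samples. Depth limits genes of low values, where 3 reads equal 2.56 to 3.99 normalised read counts.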

Other observations

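The symbol families, the test of shared exons, the tests of scaling and of genes with several transcripts, the final set of flanking genes, and the other splits of the samples were chosen only after the results were seen. Symbols were grouped by their letters before the first digit into 179 families of at least 8 tested genes and put through camera with a preset correlation. Of these, 6 passed downward and 7 upward, and 0 passed with an estimated correlation (smallest adjusted p 0.651). The median of all 13 kept its sign under 3 other scalings. This could hardly have failed, since median-ratio, TMM and quantile scaling moved the log2 fold changes by medians of only 0.047, 0.011 and 0.07. Several of the falling families encode calcium-binding and membrane proteins. Of 9 S100A genes, 5 fell and 0 rose (median -1.04, adjusted p 0.00143), with S100A6 falling from 3203 to 946.5 normalised read counts and S100A10, the partner of annexin A2, from 7550 to 3554. Of 11 annexin genes, 5 fell (median -0.51, adjusted p 0.0422), with ANXA4 going from 9422 to 3072. Of 11 symbols starting with TM and a digit, 6 fell (median -0.80, adjusted p 0.000667), including TM4SF1 (5831 to 3041) and TM4SF5 (2700 to 1500), and of 15 TSPAN genes 5 fell and 1 rose (median -0.29, adjusted p 0.0422). Of 10 carbonic anhydrase symbols 3 fell (median -0.37, adjusted p 0.0422). Of 19 COX symbols, mostly nuclear-encoded subunits of cytochrome c oxidase, 6 fell and 0 rose (median -0.32, adjusted p 0.0422), among them COX4I1 (10590 to 7631) and COX7B (2069 to 1250).

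The rising families hold genes of ribosome assembly, nuclear pores, translation and zinc finger proteins. Of 9 UTP genes, which encode small-subunit processome factors, 4 rose and 0 fell (median 0.47, adjusted p 0.0127), with UTP18 going from 1534 to 2274 and UTP20 from 2180 to 3068. Of 8 RRP genes 3 rose (median 0.26, adjusted p 0.029), of 16 nucleoporin (NUP) genes 3 rose (median 0.31, adjusted p 0.00778), of 14 RAD genes 3 (median 0.41, adjusted p 0.0359) and of 27 RBM genes 3 (median 0.19, adjusted p 0.0422), with 0 falling in each. Of 43 EIF genes, 5 rose and 1 fell (median 0.20, adjusted p 0.0235), and of 347 ZNF genes 24 rose and 8 fell (median 0.16, adjusted p 0.00778). Over members with 1 RefSeq transcript the medians were 0.22 for UTP, 0.15 for NUP, 0.20 for RAD, 0.14 for RBM, 0.13 for EIF, 0.16 for ZNF and 0.26 for RRP. Named members of these families were chosen after their values were seen.

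Genes next to each other among the 6929 with a mean of at least 20, whatever genes or distance lie between them, changed at least 2-fold in the same direction more often than shuffled genes. There were 46 such pairs, 43 of them falling, against a mean of 22.5 over 10000 shuffles (one-sided permutation p = 0.0001, the smallest these shuffles can give); falling pairs include TFF3 with TFF2 and TFF1, and CLDN3 with CLDN4. A copy number difference reaching 1 Mb around most of the falling pairs is argued against by the 429 other genes there, pooled over these pairs. Their median log2 fold change was -0.113 (95% bootstrap interval -0.163 to -0.077), above the -0.25 set as a bound. This median was still lower than the -0.029 of all genes outside pairs, and 29 of the 429 genes fell at least 2-fold. A pooled median cannot show a loss at single pairs, so such losses and smaller segments stay open. Reads shared between tandem paralogs or overlapping genes are argued against as well, since 38 pairs with different symbol stems and 43 pairs that do not overlap remained, above the upper ends, 31 and 30, of the central 95% of the shuffles. Shared regulation of neighbouring genes after EPHA2 knockdown may account for the excess and stays open as a hypothesis, which no test here addressed directly.

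Of the genes changed at least 2-fold, 79.1% were lower after knockdown. Under 3 other scalings of the libraries the share was still 70.4% where it was lowest, with quantile normalization. Median-ratio, TMM and quantile scaling moved the log2 fold changes by medians of only 0.047, 0.011 and 0.07. This check could therefore hardly have failed, and it cannot exclude a larger error of scaling. Among all called genes, whatever their fold change, the share lower went from 67.6% to 52.7% with quantile normalization. The lower depth of the knockdown libraries is argued against by thinning every library to 6937938 reads, after which the share in edgeR was 77.3%. Genes with several transcripts do not carry the excess either, since the share was 84.1% among genes with 1 RefSeq transcript. An effect of EPHA2 loss, an off-target effect of the hairpin and a difference between cultures that arose during selection could each give such an excess and stay open, as 1 control and 1 target condition do not separate them.

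Subunits of ubiquitous complexes with at least 2 RefSeq transcripts had medians 0.0039 times those of subunits with 1 (95% bootstrap interval 0.002 to 0.0075). Counting that drops reads lying in exons shared by several transcripts of a gene may account for this. Across 171 such genes, which are not independent replicates, the value rose with the percent of exon bases that belong to 1 transcript only (Spearman rho 0.249, 95% bootstrap interval 0.113 to 0.387, permutation p = 0.0008). Reads shared with pseudogenes are argued against by a ratio of 0.0042 among genes with no named pseudogene, and reads shared with overlapping genes by a ratio of 0.0052 among genes without exon overlap. No biological explanation was tested.

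The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. As many higher genes as the real 621, as many lower genes as the real 1296, and as many genes of at least 2-fold change as the real 621 came from 1 split each, the real one, and the highest other count was 2 for each. As many lists past camera as the real 2 came from 4 splits, with 2 as the highest other count. Every split but the real one puts libraries of both groups on each side, so a difference between the groups adds to the spread within the sides. Low gene counts there can follow from that alone and give no measure of chance.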
